A study of Bos taurus with 55 samples.

How the data were processed

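The data were 55 RNA-seq libraries of laser-captured luminal epithelium, glandular epithelium and stroma from endometrial biopsies of 24 Holstein cows. Per the labels' protocols, full-length cDNA was made from 2.5 ng of total RNA with the SMART-Seq v4 kit and amplified by 10 PCR cycles, and libraries were made with the Nextera XT kit and 12 further cycles. These kits do not mark the strand and add no molecular identifiers, so reads are not independent molecules, and limits given for a count of 0 cover counting error only. Per the submitters' processing notes, reads were demultiplexed with bcl2fastq 2.17.1.14 and quantified with Salmon against build ARS-UCD1.2; the Salmon version, its settings and the annotation release are not given in the sources used here.

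Per the file headers, the authors deposited a Salmon table for each library with an estimated count, a TPM value and an effective length for each of 37925 transcripts. The deposited estimated counts are not normalized. Salmon divides reads that match several transcripts among them, and in the median library 74.3% of the detected transcripts (70.4 to 77.0% over libraries) had an estimate that was not whole. The deposited TPM values are scaled by the authors' tool to transcript length and depth within a library, and together with the effective lengths served only for the length correction below. Estimated counts were rounded to whole numbers before any test. Totals were 24819502 to 40217632 reads per library, so that 1 read was worth less than 0.1 CPM. No pair of libraries of the same compartment and health group agreed within sampling noise (lowest chi-square per degree of freedom 56.9), so none was treated as a duplicate. Pairs across these groups were not compared.

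Health group, compartment and cow were taken from the labels. Each cow belongs to 1 health group and gave at most 1 library per compartment. The reference table (assembly ARS-UCD2.0) matched 0 of the transcript identifiers, and the files do not pair them with genes. The plan fixed before the data were examined was to sum estimates to genes, to test gene lists with fry and camera, and to give marker levels per library. None of these list tests or marker levels could be run, and all tests were made per transcript, as the plan allowed. A gene whose transcripts change in opposite directions, or whose reads are divided differently between libraries, gives transcript changes that a sum over the gene would not.

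The main test was the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3: filterByExpr on the groups, TMM scaling, estimateDisp, glmQLFit with robust estimation and glmQLFTest, with Benjamini-Hochberg adjustment and a threshold of 0.05. All p-values are 2-sided, except those of the share of variance between groups and of the covariance between glands and stroma. These 2 kinds count only splits with a value at least as large as the real one. The 9 comparisons of health groups used 1 fit per compartment with all 3 groups, on 25428 glandular, 24545 stromal and 26294 luminal transcripts. The 3 comparisons of compartments and the 5 interactions used all 55 libraries and 29804 transcripts with the cow as a block. Contrasts of luminal libraries with H were left out of the interactions because there are 2 such H libraries. Log2 CPM used a prior count of 2. The pairing of compartments comes from the cow numbers in the labels. As a check, deviations from group means were correlated across transcripts: same-cow r was 0.0951 to 0.313 for 18 pairs of glandular and stromal libraries, 0.0747 to 0.220 for 12 luminal and stromal pairs and 0.0137 to 0.349 for 13 luminal and glandular pairs. Among libraries of the same health group only, 18, 11 and 10 of them matched their own cow best.

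The rule for named transcripts, fixed before the data were examined, asked for an adjusted p under 0.05, a gene symbol, a group mean of at least 5 CPM and at least 80% of the libraries of each group on the fold's side of the other group's median, ranked by log2 fold change. No transcript has a symbol here. The 4 identifiers named are the leaders of that rule without its symbol condition: 1 in PE against H glandular libraries, 2 in glandular against stromal libraries and 1 in luminal against stromal libraries. Without that condition, 4047 transcripts higher and 3671 lower in glands than in stroma passed the rule. Levels are means ± SD of CPM over cows. A fold against a group at 0 uses 3 reads over the whole group.

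Compartment signals were defined after the data were seen, from 100 transcripts per compartment with the strongest differences and a mean of at least 20 CPM. Groups were compared in signal by exact permutation of log2 values (pseudocount 0.1%). Global differences between groups were tested by exact permutation, or 100000 random permutations for 3 groups, of the share of variance of log2 CPM between groups. Alternatives were RLE size factors, no filter on low counts, an offset for transcript length, only the compared groups in the fit, DESeq2 1.42.0 (the tool the series names), limma 3.58.1 voom with library weights, limma voom over all 55 libraries with the cow as a replicate block by estimated correlation (0.230), fits without the block, and leaving out each library in turn. Added after the data were seen were the signal of the other compartment as a covariate and leaving out the 4 libraries with more than 25% of it. Comparisons were repeated on up to 100 splits of the same libraries into groups of the same sizes, or 21 for the blocked fits and DESeq2, the real split included. Blocked fits on other splits held the trended dispersion of the real one, and the interactions used 5000 random transcripts.

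Each main comparison and interaction by edgeR was tested on simulated data: counts were drawn from the means and spread of the real libraries with 200 transcripts changed 2-, 4- or 8-fold. DESeq2, limma and the permutation tests were not tested in this way. Given its mean, each count was drawn independently, so deviations of a library shared by many transcripts were not simulated. Over the 25428 glandular transcripts, edgeR recovered 11.9%, 46.3% and 48.5% of the 2-, 4- and 8-fold changes between PE and H. In 3000 simulated transcripts with the cow as a block it recovered 49.3%, 70.1% and 77.3% between glandular and stromal libraries. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15, and tables were read with data.table (version 1.17.8) and jsonlite 2.0.0.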

Results

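Subclinical endometritis is an inflammation of the uterine lining without outward signs, found by counting neutrophils in a smear of uterine cells. The study asked how the endometrium of dairy cows with and without this condition differs in its transcription, compartment by compartment. Biopsies came from 24 Holstein cows 44 days after calving in the series description, or 45 days in the sample protocol. Smears read at 21 and 44 days placed 6 cows in a healthy group (H), 7 in a group that had recovered (R) and 11 in a group with persistent disease (PE). Laser capture microdissection cut 3 compartments out of the biopsies: the luminal epithelium that lines the uterine cavity, the glandular epithelium of the uterine glands, and the stroma, the connective tissue between them. Each cow gave at most 1 library per compartment, 55 in all, so the cow was the replicate; cows carry the names of their labels, such as G_6480. Glandular libraries came from 4 H, 6 R and 10 PE cows, stromal libraries from 5 H, 7 R and 10 PE cows, and luminal libraries from 2 H, 5 R and 6 PE cows.

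Estimated reads per library ran from 24819502 to 40217632 over 37925 transcripts. Transcripts with at least 10 estimated reads numbered 22140 ± 548 (SD, n = 20) in glandular, 21478 ± 556 (n = 22) in stromal and 21777 ± 495 (n = 13) in luminal libraries. The 50 most abundant transcripts took 15.1% ± 2.36 of the reads in glandular, 19.7% ± 2.2 in stromal and 18.1% ± 2.71 in luminal libraries. The files do not pair transcript identifiers with gene names, so results are given per transcript and at most 2 identifiers that rose and 2 that fell are named. All 11 H and all 18 R libraries were labelled as re-analysed from earlier records, against 0 of the 26 PE libraries. A difference between PE and either other group therefore cannot be told apart from a difference between these sets of libraries, whereas R and H were compared within 1 set.

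Libraries separated by compartment on the leading axes of the data. On principal component 1, which held 23.2% of the variance of log2 CPM (reads scaled to a common library total), every stromal library lay above every epithelial library. Component 2, with 9.27%, placed the luminal libraries above the glandular ones. Compartment took 29.0% of the variance over 29804 transcripts, the individual cow added 38.9%, and the cow's health group added 4.42%. Factors with as many levels and no effect would take 3.70%, 31.4% and 2.73%. The 2.73% treats the libraries of a cow as independent. Health groups differ only between cows, so it is too low a mark for the 4.42%. Libraries of the same cow resembled each other across compartments. After subtraction of group means, the glandular and stromal libraries of a cow correlated across transcripts with a mean r of 0.201 (18 cows), against a mean of -0.0249 for libraries of different cows of a group. What part of this came from RNA of 1 compartment in the capture of another was not tested.

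**Figure D1:**
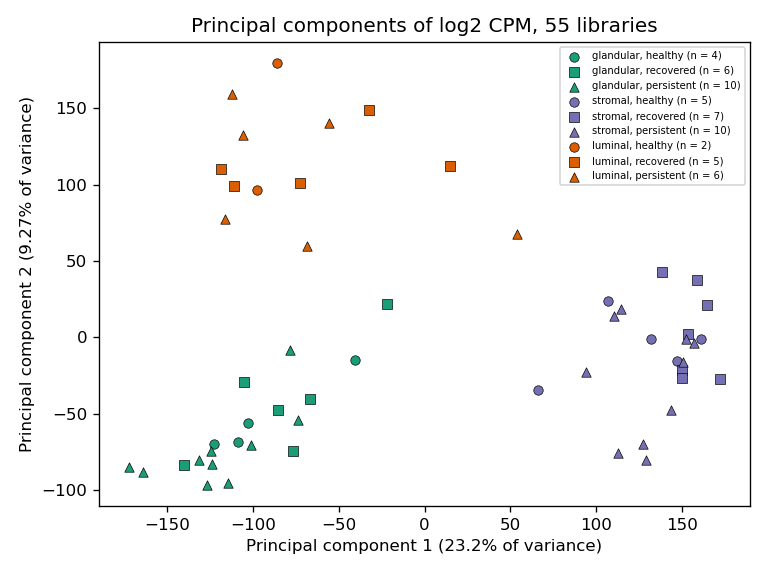
Principal components 1 (horizontal, 23.2% of the variance) and 2 (vertical, 9.27%) of log2 CPM, with 1 point per library; colour gives the compartment and shape the health group, with n in the key. The 3 compartments separate, the stromal libraries all lie to the right of 66.1 on component 1, and the health groups overlap within each compartment.

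Glandular epithelium and stroma differed in a large part of what they transcribed. Of 29804 transcripts, 13858 (46.5%) passed the test, 7210 higher in glands and 6648 higher in stroma, and 2986 and 2028 of these differed by more than 4-fold. ENSBTAT00000082092.1 was at 56.8 ± 54.1 CPM in glandular libraries (SD, n = 20, 4 of them at 0) and at 0 in all 22 stromal libraries, which makes it at least 11768-fold higher in glands (edgeR, adjusted p = 7.01e-05). ENSBTAT00000045695.3 was at 24.4 ± 11 CPM in stroma (10.5 to 47.6, n = 22) and at 0 in all 20 glandular libraries, at least 4696-fold lower in glands (adjusted p = 4.25e-08). These bounds take 3 reads over the whole group as the most that a count of 0 allows, and cover counting error only. The test was edgeR's quasi-likelihood test with the cow as a block, and 18 cows gave both libraries. Estimates of 0 rest on how reads were divided among transcripts of similar sequence, and the 24.4 CPM of ENSBTAT00000045695.3 would have left 39.7 to 295 reads in the glandular libraries at the stromal signal measured in them.

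Luminal epithelium was set apart from stroma by a similar number. There were 12493 transcripts past the test (41.9%), 6702 higher in luminal epithelium and 5791 higher in stroma, with 2710 and 2010 of them beyond 4-fold. ENSBTAT00000072951.1 was at 7.51 ± 5.31 CPM in luminal libraries (n = 13, 2 of them at 0) and at 0 in all 22 stromal libraries, at least 1554-fold higher in luminal epithelium (edgeR, adjusted p = 8.47e-06). The same transcript was at 4.74 ± 3.40 CPM in glandular libraries, and the difference did not pass (log2 fold change 0.64, SE 0.997, edgeR adjusted p = 0.690). ENSBTAT00000045695.3 was at 0 in 12 of 13 luminal libraries and at 11.8 CPM in that of PE cow E_2333, a mean of 0.905 CPM. Its log2 fold change against stroma was -9.97 with the cow as a block (SE 1.06, adjusted p = 2.71e-06) and -4.74 with no block. It was -12.6 without the libraries with more than 25% signal of the other compartment, which include that of E_2333. The size of this fold thus depends on the model and on the libraries used. The comparison rested on 12 cows with both libraries.

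Fewer transcripts separated the epithelia from each other than from stroma: 7827 (26.3%) passed, 3848 higher in luminal and 3979 higher in glandular epithelium, 1087 and 1337 of them beyond 4-fold. ENSBTAT00000082092.1 was at 18.4 ± 21.9 CPM in luminal libraries (5 of 13 at 0), and its difference from the glandular level did not pass (log2 fold change -1.56, SE 1.66, edgeR adjusted p = 0.544). Over the 3 comparisons, 18265 transcripts (61.3%) differed between some pair of compartments. Of the transcripts that separated epithelia from stroma, 4512 were higher in both epithelia and 3903 were lower in both, where independent lists of these sizes would share 1621 and 1292. Both comparisons use the same stromal libraries. With no effect at all, simulated libraries gave 63 and 42 calls higher in the epithelia and shared 17, where independent lists would share 0.0888. In the other direction, lists of 56 and 3 shared 0. The simulation was run only with the same stromal libraries in both comparisons, and not with these divided. It therefore cannot show whether sharing them caused this overlap. These simulated libraries had no effect of the cow and were fitted with no block. With each stromal library used in 1 comparison and no block, 3268 and 2544 were shared, against 1288 and 960 for independent lists. In sets that overlap with these, 2094 transcripts were higher in glands than in both other compartments and 1916 were higher in luminal epithelium than in both others. Separate from the 4512 and 3903, 362 moved in opposite directions against stroma in the epithelia. The luminal against glandular test had 13 cows with both libraries.

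Transcripts typical of a neighbouring compartment were present at low levels in most captures. For each compartment, the 100 transcripts with the strongest difference and a mean of at least 20 CPM were taken from these libraries after the data were seen, and the median over a set of their levels, each as a percent of the level in its own compartment, was taken as the signal of that compartment. The stromal set stood at a median of 12.4% in glandular libraries (4.43 to 39.0%) and 8.88% in luminal libraries (4.43 to 68.2%). The set shared by the epithelia stood at 1.43% in stromal libraries (0.0203 to 20.7%). Low levels elsewhere are partly built in, as the sets were picked for log2 differences of at least 2.41 (stromal) and 4.93 (epithelial). The stromal and epithelial percentages are therefore not comparable with each other. Luminal transcripts stood at 4.82% in glandular libraries and glandular transcripts at 5.92% in luminal ones. Over 25% were the luminal library of PE cow E_2333 (68.2%), the glandular library of H cow G_6480 (39.0%), and the luminal (37.6%) and glandular (29.0%) libraries of R cow R_6545. The stromal signal in glandular libraries was 11.1% ± 4.62 in PE (n = 10), 19.8% ± 6.85 in R (n = 6) and 18.7% ± 13.6 in H cows (n = 4). PE lay below R by an exact permutation test of log2 values (two-sided p = 0.0211), but not after adjustment over the 6 tests of glandular libraries (0.127), and with the mean over the set in place of the median p was 0.0707. Luminal signal in glandular libraries was 3.75% ± 1.77 in PE and 7.97% ± 5.44 in H cows (exact p = 0.0430, adjusted 0.129, and 0.0829 with the mean over the set). Among the H cows, G_6480 had 16.1%. The others had 4.82 to 6.16%, within the 1.67 to 6.76% of PE cows.

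**Figure D2:**
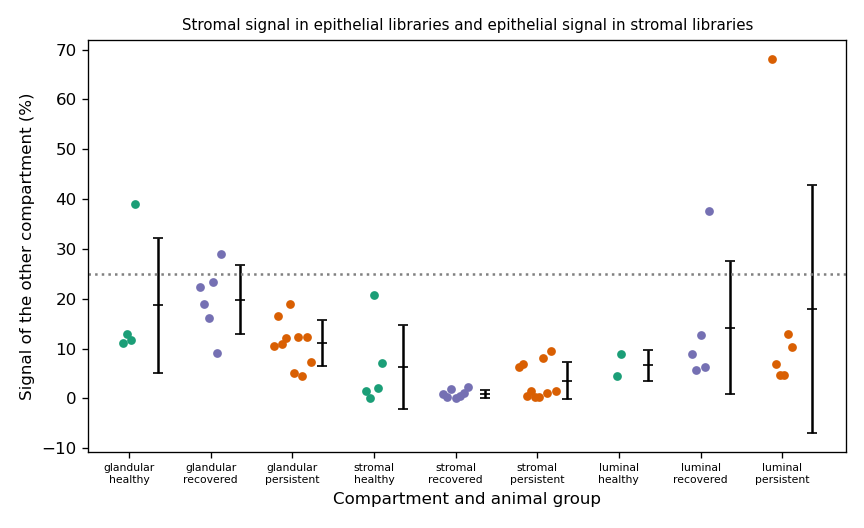
Signal of the other compartment in percent (vertical axis) for each library, by compartment and health group (horizontal axis): stromal signal in glandular and luminal libraries, epithelial signal in stromal libraries. Points are libraries, bars are the mean ± SD, and the dotted line marks 25%, above which 4 libraries lie, the highest at 68.2%.

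In glandular epithelium, persistent disease was compared with health. ENSBTAT00000066294.2 fell by 2.57 on the log2 scale in PE (SE 0.36, edgeR adjusted p = 0.0210), the 1 transcript of 25428 that passed. It was at 6.86 ± 2.29 CPM in PE (3.53 to 10.6, n = 10), at 13.3 ± 2.46 CPM in R (9.97 to 16.1, n = 6) and at 40.7 ± 42.6 CPM in H cows (n = 4), where cow G_6480 had 105 CPM and the others 17.7 to 20.5. All 4 H libraries lay above all 10 PE libraries. Without cow G_6480 the log2 fold change was -1.50 (SE 0.262) with adjusted p = 0.442. The call was also lost on leaving out PE cow E_2333, E_4423, E_4454, E_5638, E_6523 or E_6575, with the fold nearly unchanged (-2.57 to -2.50, SE 0.378 to 0.386, adjusted p 0.0571 to 0.0650). Leaving out H cow G_4463, G_5645 or G_6450 gave 6, 11 and 12 transcripts. Unadjusted p was under 0.05 for 2484 transcripts. edgeR called 0 with only the 2 groups in the fit (ENSBTAT00000066294.2 at -2.58, SE 0.410, adjusted p = 0.318), 0 with the signal of the other compartment as a covariate (-2.10, SE 0.450, adjusted p = 0.558) and 0 without the libraries over 25% signal, which leaves out G_6480 (-1.50, SE 0.265, adjusted p = 0.615). DESeq2 called 175 but gave this transcript no adjusted p, and limma with the cow as a replicate block over all 55 libraries called 3 others (0.202). With library weights, limma called 1 transcript, not this one (0.0832).

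**Figure D3:**
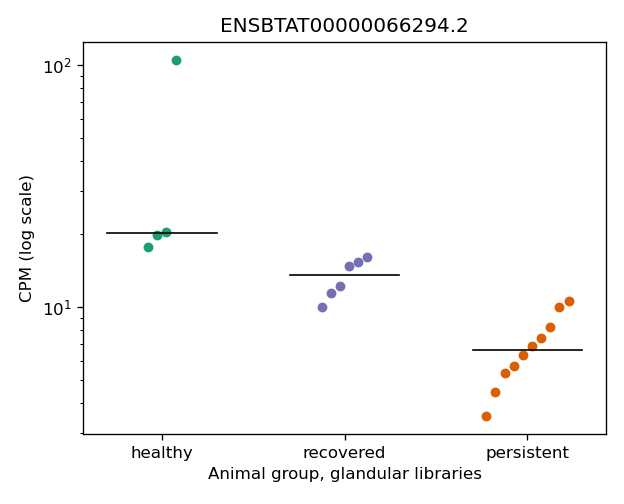
Level of ENSBTAT00000066294.2 in CPM (vertical log axis) in the glandular libraries of the healthy, recovered and persistent groups (horizontal axis); points are libraries and lines are group medians. The H libraries lie at 17.7 to 20.5 CPM with 1 at 105, and the PE libraries at 3.53 to 10.6.

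The glands of recovered cows were compared with those of healthy cows and with those of cows whose disease persisted. edgeR called 0 of 25428 transcripts between R and H, with 2230 at an unadjusted p under 0.05 and a smallest adjusted p of 0.358. ENSBTAT00000066294.2 had a log2 fold change of -1.61 (SE 0.42, adjusted p = 0.481). DESeq2 called 130 transcripts, limma with the replicate block 5, limma with library weights 0 and edgeR on these 2 groups alone 3. Between PE and R, edgeR called 0 as well, with 1973 at an unadjusted p under 0.05 and a smallest adjusted p of 0.405, and ENSBTAT00000066294.2 at -0.96 (SE 0.34, adjusted p = 0.551). DESeq2 called 105, limma with the block 3, and limma with library weights 1. In simulated libraries of these sizes, edgeR recovered 11.9% of transcripts changed 2-fold and 46.3% of those changed 4-fold between PE and H, 1.49% and 40.3% between R and H, and 13.4% and 61.2% between PE and R. False calls made up 4.05%, 1.37% and 8.91% of all simulated calls in the same order. Simulated counts were drawn independently for each transcript, so these shares need not hold for the real libraries. There, another split of the PE and R glandular libraries gave 385 calls.

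The stroma showed no transcript past edgeR's threshold in any comparison of health groups, out of 24545. PE against H gave 0, with 1834 at an unadjusted p under 0.05, while DESeq2 called 176 and limma with the replicate block 5. R against H gave 0, with 2613 at an unadjusted p under 0.05, while DESeq2 called 170, limma with the block 3 and edgeR on these 2 groups alone 1. PE against R gave 0, with 2831 at an unadjusted p under 0.05 and a smallest adjusted p of 0.188, while DESeq2 called 183 and limma with the block 8, and edgeR called 1 without R cow R_5614 or without R cow R_6492. With library weights, limma called 0 in each of these 3 comparisons. ENSBTAT00000066294.2 was at 9.26 ± 6.0 CPM in PE (n = 10), 6.79 ± 2.67 in R (n = 7) and 52.5 ± 88.1 in H cows (n = 5), with 209.5 CPM in H cow G_6480 (PE against H, log2 fold change -2.50, SE 0.70, edgeR adjusted p = 0.57). Over all transcripts together, the R and H groups accounted for 12.1% of the variance between their 12 stromal libraries, against a mean of 9.09% over splits of the same libraries (exact permutation p = 0.00884, adjusted over 12 such tests 0.106). This was the smallest p of the 12. The others in stroma were 0.0203 for the 3 groups together, 0.0539 for PE against R and 0.153 for PE against H. In glands they were 0.0711 to 0.176, and in luminal libraries, where the groups took less than the mean over splits, 0.476 to 0.893. Epithelial signal in these libraries was 3.58% ± 3.65 in PE, 0.975% ± 0.816 in R and 6.29% ± 8.50 in H cows, with no difference past an exact permutation test (smallest p 0.126, and 0.0984 with the mean over the set).

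Luminal epithelium, compared in 2 H, 5 R and 6 PE cows, had no transcript past edgeR's threshold either. PE against H gave 0 of 26294 transcripts by edgeR, with 639 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0721. DESeq2 called 133, limma with the replicate block 14 and limma with library weights 1, and edgeR called 1 without PE cow E_5638 and 4 without H cow G_6480. R against H gave 0, with 1074 at an unadjusted p under 0.05, while DESeq2 called 127 and limma with the block 8, and edgeR called 4 without H cow G_6480. PE against R gave 0, with 1124 at an unadjusted p under 0.05, while DESeq2 called 30 and limma with the block 1, and edgeR called 1 without PE cow E_5638. In these last comparisons, of R with H and of PE with R, limma with library weights called 0. Of DESeq2's calls in the 3 luminal comparisons, 89.5%, 82.7% and 83.3% had most of their CPM in 1 library or a group at 0. By edgeR, unadjusted p was under 0.05 for 2.43%, 4.08% and 4.27% of luminal transcripts in these comparisons. Uniform p-values, as with no effect, would give a share of 0.05, so these luminal counts lie below it. The glandular and stromal comparisons gave 7.47 to 11.5%. Without cow G_6480 a single H library was left, which was then assumed to vary like the other groups. ENSBTAT00000066294.2 was at 18.5 ± 7.75 CPM in PE (n = 6), 26.3 ± 14.4 in R (n = 5) and 19.2 ± 12.8 in H cows (n = 2). In simulated luminal libraries, edgeR recovered 1.49% of transcripts changed 4-fold between PE and H and 10.6% of those changed 8-fold.

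Whether a health group's effect differed between compartments was tested as an interaction with the cow as a block. edgeR called 0 of 29804 transcripts in each of 5 such tests. In simulated data it recovered few such differences. Between glandular and stromal libraries these were 5.97% at 2-fold and 22.4% at 4-fold for PE against H, and 2.99% and 23.9% for R against H. For PE against R, over the pairs of compartments, 10.4 to 20.9% were recovered at 2-fold and 32.8 to 50.7% at 4-fold. Unadjusted p was under 0.05 for 1173 transcripts (3.94%) in PE against H, 551 (1.85%) in R against H and 1691 (5.67%) in PE against R between glandular and stromal libraries. The counts were 1733 (5.81%) and 944 (3.17%) in PE against R between luminal and stromal and between luminal and glandular libraries. Uniform p-values would give a share of 0.05. DESeq2, fitted with no replicate block, called 209, 215, 202, 215 and 172 in the same order. An effect in 1 compartment and not in another is therefore not shown to differ between them.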

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

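The tests of cow G_6480, of the transcript called in glandular libraries and of cow E_2333 were chosen after the results were seen, and so were the splits of the libraries reported here, except those by DESeq2 other than PE against H in glandular libraries. In each group of 4 to 10 libraries, 5 measures were searched for a library far from all others, and 13 of the 40 combinations of group and measure held one. The critical values of this rule flag about 1 in 20 groups by chance if values are normally distributed, which was not tested here. The 5 measures are not independent, since cow R_6545 and cow G_6480 appear in several, and 1 of them is a transcript picked from these data.

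In the signal of another compartment, the libraries that stood out were the glandular library of H cow G_6480 with 39.0% stromal signal (the other H libraries at most 12.8%), the luminal library of PE cow E_2333 with 68.2% (others at most 12.9%) and the luminal library of R cow R_6545 with 37.6% (others at most 12.7%). Counts of transcripts at least 4-fold above all other libraries of the compartment were 96 in the glandular library of G_6480 (the other H libraries at most 3), 34 in that of E_2333 (next 17) and 40 in that of R_6545 (next 10). For R_6545 they were also 78 in the luminal library (next 22) and 19 in the stromal library (next 9). The glandular library of R_6545 had 20759 transcripts with at least 10 reads, the fewest of its group (next 21779). The glandular library of PE cow E_6523 had 40217632 reads (next 31608123). ENSBTAT00000066294.2 stood at 105 CPM in the glandular (next 20.5) and 209.5 CPM in the stromal library (next 26.0) of G_6480, and at 22.9 CPM in the stromal library of PE cow E_5777 (next 12.1).

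In cow G_6480, 33 transcripts were at least 4-fold above every other library of the compartment in both its glandular and its stromal library, where 0.187 would be shared by chance. ENSBTAT00000066294.2 is one of them. In the glandular library these 33 stood at a median of 35.4% of their level in the stromal library of the same cow (quartiles 29.0 and 45.0%), at the lower quartile of the 100 stromal transcripts there (35.4 and 54.0%) and inside it by a margin far below this spread. Stromal RNA in the glandular capture may account for the glandular level of these 33, but it leaves open why they are high in the stroma of this cow, for which no biological explanation was tested. All 96 transcripts high in the glandular library stood at a median of 55.7% (quartiles 39.8 and 73.3%), above the upper quartile of the stromal transcripts but within the spread, and 15 of them lay above the cow's own stromal level. The other 63 stood at 67.7% (quartiles 54.1 and 93.4%), above the quartiles of the stromal transcripts, but leaving out those high in stroma raises this value by itself. Whether stromal RNA is the only source of the 96 cannot be told apart from another source here, as they were picked for a high glandular level. Without G_6480, ENSBTAT00000066294.2 had a log2 fold change of -1.50 (SE 0.262) between PE and H in place of -2.57 (SE 0.365), the 3 other H libraries (17.7 to 20.5 CPM) still lay above all 10 PE libraries (at most 10.6 CPM), and the call ended at adjusted p = 0.442. Since the transcript was picked for this difference and all H libraries come from earlier records and no PE library does, disease, library set and chance cannot be told apart here: 9 of 100 splits of the PE and H glandular libraries called at least 1 transcript by edgeR, and up to 5 in another split.

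The luminal library of cow E_2333 carried the stromal set at 68.2% and the epithelial set at 23.7%, below the 55.4 to 194% of the other 12 luminal libraries. The luminal set, at 45.3%, lay within the 14.0 to 254% of these 12. ENSBTAT00000045695.3 stood in the library at 11.8 CPM, 48.3% of its mean over all stromal libraries, and at 0 in those 12. The stroma of E_2333 itself had 12.8 CPM. The transcript does not follow the stromal signal, since the luminal library of R_6545 had 0 reads at a signal of 37.6%. At the mean over all stromal libraries 255 reads would match that signal, and fewer at the 10.5 CPM in the stroma of R_6545. A swap with the stromal library of E_2333 is argued against by that library, whose epithelial signal was 7.0%, below every luminal library. A luminal capture that took up stroma may explain the low epithelial signal (23.7%) beside the high stromal one, whereas the luminal set varies too widely between libraries to add to this. No biological explanation was tested, as no other cow has such a library.

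DESeq2, the tool that the series names, called 105 to 183 transcripts between health groups of glands or stroma where edgeR called 0 or 1. Other splits of the same libraries gave DESeq2 as many calls: of 21 splits, the real one included, 3 did so for PE against H (175 calls, highest other 436), 6 for R against H (130, 329) and 4 for PE against R (105, 389) in glandular libraries, and 3 (176, 207), 3 (170, 191) and 5 (183, 352) in stromal libraries in the same order. For PE against R in luminal libraries 14 of 21 did (30, 275), so chance cannot be excluded for any of these 7 counts. Of the transcripts called, those with most of their CPM in 1 library or with a group at 0 were 42.9%, 58.5% and 28.6% in glands and 38.6%, 52.4% and 19.1% in stroma, and 89.5%, 82.7% and 83.3% in luminal libraries. Calls that owe nothing to the health groups may thus make up part of these counts, but medians over the other splits of glands and stroma were lower than the real counts, at 62.5, 73, 30, 35.5, 50 and 8.5 calls, so an effect of the health groups stays open there. For PE against R in luminal libraries the median, 56.5, was higher than the real 30.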

How the results depend on the processing

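Alternatives using the signal of the other compartment or leaving out the libraries over 25% of it were chosen after the data were seen, and all others before the data were examined. Tests of gene lists by fry and camera, and marker levels by median in place of mean, were not run, as no gene names could be paired. The cause of the changes below was not tested unless stated. Counts of transcripts between compartments stayed within 1.5 times under every alternative run (13766 to 15036 glandular against stromal, 12234 to 13918 luminal against stromal, 7628 to 9584 luminal against glandular), the fits without the block included. RLE size factors (17 results), no filter on low counts (12) and a length offset (12) changed no count between health groups and no count between compartments by more than 1.5 times. RLE size factors changed no interaction count.

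Between health groups, counts are in the order PE against H, R against H, PE against R. DESeq2 called 175, 130 and 105 transcripts in glandular, 176, 170 and 183 in stromal and 133, 127 and 30 in luminal libraries, and with no replicate block 209, 215, 202, 215 and 172 in the 5 interactions. The limma fit of all 55 libraries with the cow as a replicate block called 3, 5 and 3 in glandular, 5, 3 and 8 in stromal and 14, 8 and 1 in luminal libraries. It differs from the main test in the tool, in the libraries fitted and in the block, so that these counts are not assigned to any one of them. Leaving out the block changed no interaction count by edgeR. With only the compared groups in the fit, edgeR called 0 for PE against H and 3 for R against H in glandular libraries and 1 for R against H in stromal libraries. With library weights, limma called 1 transcript other than ENSBTAT00000066294.2 for PE against H and 1 for PE against R in glandular and 1 for PE against H in luminal libraries, and 0 in the other 6 comparisons. PE against H in glandular libraries gave 0 with the signal of the other compartment as a covariate (ENSBTAT00000066294.2 at -2.10, SE 0.450, against -2.57, SE 0.365, in the main test) and 0 without the libraries over 25% (-1.50, SE 0.265).

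Leaving out each library in turn gave 0 to 12 calls for PE against H in glandular libraries, 0 to 1 for PE against R in stromal libraries, and 0 to 4 for PE against H, 0 to 4 for R against H and 0 to 1 for PE against R in luminal libraries. The counts above the real one came without H cows G_4463 (6), G_5645 (11) and G_6450 (12), R cows R_5614 or R_6492 (1 each), H cow G_6480 (4 and 4) and PE cow E_5638 (1). The other 4 comparisons stayed at 0 throughout. ENSBTAT00000066294.2 kept its direction in 8 alternatives (log2 fold change -2.59 to -1.50, adjusted p 0.0212 to 0.615), passing in 3 and not in 5, and DESeq2 gave it no adjusted p. With 1 library left out it passed in 7 of 14 fits (adjusted p 0.00864 to 0.442). The other 3 named transcripts kept their direction and call in all 6 alternatives, but not the size of their folds. Log2 fold changes ran from -14.1 to -4.74 for ENSBTAT00000045695.3 between luminal libraries and stroma (main test -9.97) and from -30 to -12.4 between glands and stroma (-14.4). They ran from 13.6 to 21.7 for ENSBTAT00000082092.1 and from 9.68 to 10.9 for ENSBTAT00000072951.1. The -30 and the 21.7 came from DESeq2, each against a group with 0 reads in every library. Counts of 0 set no upper limit to a fold, so these are not measured sizes. The other alternatives gave -14.4 to -12.4 and 13.6 to 13.8.

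At 24819502 to 40217632 reads per library, 1 read is worth less than 0.1 CPM, and a change in transcripts at that level was not detectable. In simulated libraries of the real sizes edgeR recovered 11.9% of 2-fold changes between PE and H in glandular libraries, 11.9% in stromal and 0% in luminal libraries, and at 4-fold 46.3%, 47.8% and 1.49%.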

Other observations

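The comparisons of effects between glands and stroma, the levels of ENSBTAT00000045695.3 and the splits below were chosen after the results were seen, except the splits of the luminal against stromal and luminal against glandular libraries, which were fixed before their results.

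Libraries of the same cow mostly resembled each other across compartments. Matches were sought among libraries of the same health group only. Of 18 cows with glandular and stromal libraries, the glandular deviations of all 18 correlated best with the stroma of the same cow, as did 11 of 12 luminal and stromal pairs and 10 of 13 luminal and glandular pairs. Between glands and stroma, the R minus H differences correlated across transcripts with r = 0.388. Splits of the same 9 cows gave a mean of 0.241 (upper-tail exact permutation p of the covariance 0.0476, and 0.179 without cow G_6480). For PE minus H r was 0.280 against 0.213 (p = 0.118) and for PE minus R 0.244 against 0.198 (p = 0.109), and after adjustment over these 3 none passed (each 0.118). Transcripts are not independent replicates, and the same cows enter on both sides. Stromal RNA in the glandular capture of the same cow could also raise these correlations, which was not tested.

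ENSBTAT00000045695.3 had 0 reads in all 20 glandular libraries and in 12 of 13 luminal libraries, although the stromal signal of these glandular libraries would have brought 39.7 to 295 reads at its stromal mean of 24.4 CPM. In the glandular library of G_6480, with 39.0% stromal signal, it had 0 reads where 295 would match that signal. These numbers use the mean over all stromal libraries, which ran from 10.5 to 47.6 CPM, and not the stroma of the same cow. Whether reads of ENSBTAT00000045695.3 were assigned to another transcript of the same gene was not tested, since the files do not pair transcripts with genes.

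For the counts between compartments, no other split reached the real count. For glandular against stromal libraries, 1 of 21 splits that exchanged compartments within cows, the real one, reached it (13857 with the dispersion held). The highest other had 8393 transcripts. This is the smallest share that 21 splits allow, and it was not adjusted over the comparisons. The same holds for luminal against stromal (1 of 21, 12492 against 5427) and luminal against glandular libraries (1 of 21, 7823 against 3140). Of the 20 other splits, 3, 2 and 5 called any transcript.

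Of the 7 counts by edgeR between health groups that were split, only the count of 1 could be tested, and chance could not be excluded for it. Every split reaches a real count of 0, so nothing was tested there. PE against H and R against H in luminal libraries, with 2 H cows, were not split. As many calls as the real 0 or 1 were made in 9 of 100 splits for PE against H in glandular libraries (highest other 5), and necessarily in 100 of 100 where the real count was 0: R against H (highest other 3) and PE against R (385) in glandular, PE against H (258), R against H (57) and PE against R (2) in stromal, and PE against R (1) in luminal libraries. Most of the other splits called none, as 8 of 99 called any transcript for PE against R in glandular and 6 of 99 for PE against H in stromal libraries, and what set apart those with 385 and 258 calls was not tested. By unadjusted p under 0.05, 4 of 100 splits reached the 2613 transcripts of R against H in stroma (median of the others 1081), and 4 of 100 reached the 2831 of PE against R there (907). In the other 5 comparisons as many were reached by 18 of 100 splits (PE against H in stroma), 7, 10 and 21 (PE against H, R against H and PE against R in glands) and 59 (PE against R in luminal libraries), and these 7 shares were not adjusted for their number. In the 5 interactions, on 5000 transcripts, all 21 of 21 splits necessarily reached the real 0, and the highest other splits had 1, 1, 1, 2 and 0 calls. By unadjusted p under 0.05, 4, 16, 3, 5 and 16 of 21 splits reached the real count, in the order given for the interactions above.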
